A study of Xenopus laevis with 11 samples.

How the data were processed

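Gene expression was measured on Affymetrix Xenopus laevis arrays in tissue dissected from frog embryos. Per the labels' protocols, embryos were grown at 15 °C, the tissue was microdissected, RNA was extracted with Trizol and columns, and 10 ug of RNA per array was labelled with biotin. The 11 arrays fell into 5 groups by their labels: animal caps grown to stage 14 (n = 1), neural plate at stage 12 (n = 2), neural border at stage 14 (n = 3), neural border at stage 18 (n = 2) and anterior neural fold at stage 18 (n = 3). The labels call the arrays biological replicates, but nothing says that they came from separate clutches or animals, so p-values measure only the spread between these samples, which may be technical.

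The deposited table held a value for each of 15611 probe sets on each array. The submitters' processing notes name R 2.14.2. The method of background correction, summary and between-array normalization is not given in the sources used here, and the deposited values, which ran from 2.13 to 13.56 with array medians between 4.94 and 5.04, were taken as log2 intensities on their range. That the arrays were already put on a common scale before deposit is read from those medians, and whether genes had also been centred or filtered stays unknown, although every array had 0 missing values. A log2 difference of 1 was read as a 2-fold difference in intensity. Intensities of a probe set were compared between arrays, never between probe sets. The 17 tag control probe sets, which should bind no frog transcript, had array medians of 2.94 to 3.23 and a 95th percentile of 3.72 over all arrays, and a level below 3.72 was treated as not told apart from background. A fold against such a level depends on that floor and understates a larger difference.

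Probe sets were named through the platform's annotation, with symbols updated by gene ID through the RefSeq gene table. Of the 15491 probe sets that are not controls, 9304 had exactly 1 symbol, 195 had several and 5992 were unnamed in the annotation used here. No gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 9227 matched the RefSeq table and 77 kept the platform's symbol. The suffixes .L and .S mark the copies of a gene on the long and short chromosomes of a homeologous pair in this allotetraploid frog. After removing them, 6485 genes were measured, 2022 of them by 2 or more probe sets. No genome was used, so no coordinates are given.

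Differences were tested with limma 3.58.1 in R 4.3.3. The deposited log2 values of all 11 arrays entered 1 linear model with a mean per group, without between-array normalization, array weights or a replicate block. The spread was moderated by eBayes without trend or robust settings, with 6 residual and 3.75 prior degrees of freedom and a prior SD of 0.16 on the log2 scale. The 120 control probe sets were left out, and p-values, all two-sided, were adjusted by Benjamini-Hochberg over the remaining 15491 probe sets within each comparison. The threshold was an adjusted p of 0.05. A standard error comes from this model, while SDs are those of the arrays of a group. The animal cap group had 1 array, so it has no SD, and it is assumed to vary like the other groups. The number of arrays limits the precision of every value.

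Gene lists were tested with limma's camera, each gene represented by its probe set with the highest mean over all arrays, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 22 lists within a comparison. Members of a list were also counted by their own test over all probe sets, and again adjusted over the list alone. Each list call was repeated with an inter-gene correlation estimated from the data. The lists, written from textbook knowledge and not from these samples, were neural border specifiers, neural crest specifiers, neural crest effector and migration genes, neural plate progenitor genes, neuronal differentiation genes, anterior neural and forebrain genes, placode and preplacodal genes, cement gland and hatching gland genes, epidermis genes, multiciliated cell genes, muscle and paraxial mesoderm genes, axial mesoderm and notochord genes, endoderm genes, blood and lateral mesoderm genes, early ectoderm and pluripotency-associated genes, Hox genes, Wnt, FGF and BMP ligands, targets and regulators, retinoic acid pathway genes, cell cycle genes and ribosomal protein genes. Some genes stand in more than 1 list, such as hesx1, pitx1 and frzb. The muscle list took in pcdh8l, a protocadherin of the same name root as its member pcdh8, by its wildcard.

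Genes were named in the text by a fixed rule. In each comparison these were the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among probe sets with 1 symbol, past the threshold and with no overlap between the arrays of the groups. Up to 4 members of each list past the threshold with the largest changes were added, or the 2 members with the largest changes where fewer than 2 passed. All probe sets of pax3 and zic1 were added because the series title names these genes. The groups, the comparisons, the tests, the lists, this rule and the alternatives were chosen before the data were examined. The overlap of 2 comparisons that share no arrays was tested with Fisher's exact test, two-sided, with a 95% confidence interval of the odds ratio and the number that independent sets would share. The comparisons do share the model's estimate of spread for each probe set, so their sets are not fully independent.

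The alternatives were quantile normalization, centring of each array on its median, leaving out probe sets below the 40th percentile of mean level, eBayes with trend and robust settings, array weights, a model of only the arrays compared, the replicate number as a block, a 2-fold minimum, averaging the probe sets of a gene, an estimated list correlation, and leaving out each array in turn. The neural crest specifier list was also tested without rpe65, an alternative chosen after seeing the data. Where a range over the alternatives is given, it leaves out the estimated list correlation, whose adjusted p stands on its own. Array quality was checked first. Pearson correlations over all probe sets were 0.983 to 0.993 within groups and 0.868 to 0.978 between groups, and no pair of arrays shared more than 28 identical values, so no array was taken for a repeat of another. The labels give no scan date or slide, so no batch could be tested. They do number the arrays, with 1 for the animal cap, 7 and 8 for the plate and 10, 5 and 6 for the stage 14 border. The stage 18 border has 11 and 12, and the anterior neural fold 14, 15 and 16. An effect of the order behind these numbers, if any, cannot be told apart from the groups.

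The test was checked on simulated values for 15491 probe sets. Of 67 probe sets changed 2-fold in simulation, 67.2% were recovered at the sizes of the stage 14 border against neural plate comparison, 65.7% for the border at stages 18 and 14, 73.1% for the border against the anterior neural fold and 47.8% for the border against the animal cap. Of 66 changed 4-fold, 93.9%, 95.5%, 98.5% and 90.9% were recovered, in the same order. Of 67 changed 1.5-fold, only 13.4%, 20.9%, 25.4% and 11.9% were recovered, so changes of that size were mostly missed in simulation. Calls on unchanged probe sets numbered 4, 17, 3 and 5. For the border stages, the 17 stood beside 14, 44 and 63 recovered at 1.5-fold, 2-fold and 4-fold. The share of false calls there was above the one that the threshold aims for. In the other comparisons it was below. In each comparison 3 of 3 lists shifted by 0.5 on the log2 scale were called, with 0 calls among unshifted lists that shared no genes with them. The simulated probe sets varied independently of each other. This check therefore cannot show how often correlated list members lead to false list calls with the preset correlation. Only the 67, 67 and 66 probe sets changed 1.5-fold, 2-fold and 4-fold differed in a simulation. That is a far smaller share than the 41% that passed against the plate. The adjustment of p-values depends on that share, so the recovered percentages do not carry over to these data. For 10000 random lists matched on mean level, a list's median was placed by its percentile.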

Results

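Transcript levels were measured on 11 arrays of Xenopus laevis tissue. The neural crest, the embryonic cell population that leaves the dorsal neural tube and forms pigment cells, peripheral neurons and facial cartilage, was followed through its induction in the early neural plate at stage 12 (n = 2), the neural border at stage 14 (n = 3) and the neural border at stage 18 (n = 2). The reference tissues were the anterior neural fold at stage 18 (n = 3), which belongs to the neural border but forms no crest, and animal cap, ectoderm grown to stage 14 (n = 1), which becomes epidermis. Each array gave log2 intensities for 15611 probe sets, with array medians of 4.94 to 5.04. Arrays of a group correlated at 0.983 to 0.993 over all probe sets. Between groups the correlations of single arrays averaged 0.976 for the neural border at stages 14 and 18, 0.971 for the stage 18 border and anterior neural fold, 0.913 for the stage 12 plate and stage 14 border, and 0.914 for the animal cap and stage 14 border.

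Zic1 and Pax3, the transcription factors named in the series title, had different profiles. The brighter of the 2 zic1.S probe sets was highest in the stage 12 neural plate, at 10.5 ± 0.16 (SD, n = 2), and lay at 9.57 ± 0.05 (SD, n = 3) in the stage 14 border, 8.91 ± 0.02 (SD, n = 2) in the stage 18 border, 8.28 ± 0.1 (SD, n = 3) in the anterior neural fold and 3.74 in the animal cap. The pax3.S probe set was variable in the stage 12 plate, at 5.81 ± 1.36 (SD, n = 2), and stood at 9.08 ± 0.06 (SD, n = 3) in the stage 14 border, 8.85 ± 0.03 (SD, n = 2) in the stage 18 border, 7.19 ± 0.68 (SD, n = 3) in the anterior neural fold and 3.01, within background, in the animal cap. Of the 4 pax3.L probe sets, 1 followed the same order, from 3.98 ± 0.99 (SD, n = 2) in the plate to 7.86 ± 0.16 (SD, n = 3) in the stage 14 border. The other 3 did not. Of these, 1 read 8.41 and another 8.98 in the animal cap, against 7.48 ± 0.99 and 7.62 ± 1 (SD, n = 3) in the stage 14 border, and the last stayed between 4.27 and 4.83 as group means. Below, pax3.L refers to the probe set that followed the order of pax3.S.

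**Figure D1:**
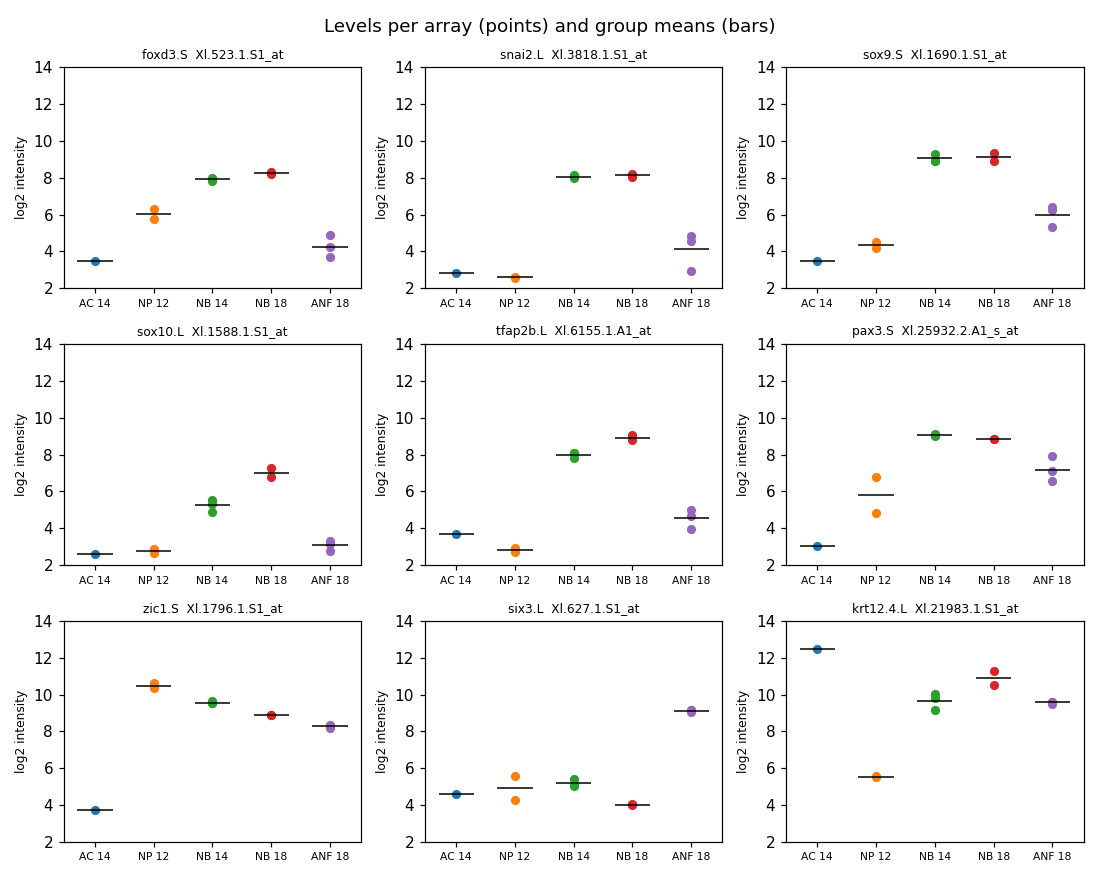
Log2 intensity of 9 probe sets (vertical axis) in the 5 groups (horizontal axis), with a point per array and a bar at each group mean; AC 14 is animal cap at stage 14, NP 12 neural plate at stage 12, NB 14 and NB 18 neural border at stages 14 and 18, and ANF 18 anterior neural fold at stage 18. The snai2.L mean lies at 8.07 and 8.13 in the neural border at stages 14 and 18, at 2.59 in the neural plate and at 4.12 in the anterior neural fold, while six3.L stands at 9.13 in the anterior neural fold and at 4.03 in the stage 18 border.

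The comparison of the stage 14 neural border with the stage 12 neural plate asked what changes as crest-forming tissue emerges from the plate. Several crest transcription factor genes rose, some of them from background. The snai2.L level was 8.07 ± 0.08 (SD, n = 3) in the border against 2.59 ± 0.06 (SD, n = 2) in the plate, a 44.6-fold difference (log2 fold change 5.48, SE 0.43, adjusted p = 9.79e-06). Likewise tfap2b.L, an AP-2 factor gene, rose 36.3-fold (log2 fold change 5.18, SE 0.26, adjusted p = 8.03e-07), and sox9.S, a SoxE factor gene, rose 26.3-fold (log2 fold change 4.72, SE 0.29, adjusted p = 2.28e-06). In the opposite direction tdgf1.3.L, which encodes a Nodal co-receptor of the Cripto family, fell 85.9-fold, from 11.29 ± 0.14 (SD, n = 2) to 4.86 ± 0.19 (SD, n = 3), with a log2 fold change of -6.42 (SE 0.22, adjusted p = 1.65e-07). In all, 6352 of 15491 probe sets (41%) changed, 3034 higher and 3318 lower in the border, and 2744 changed at least 2-fold. The plate levels of snai2.L, tfap2b.L, krt12.4.S, xa-1.L and tubb2b.S (2.59, 2.81, 3.36, 3.14 and 3.54) and the border levels of bmp4.S, cdx1.S and tbxt.S (3.14, 2.87 and 3.19) lay within the background of the tag controls. The folds given for these genes are limited by that floor. For each gene named here and in the following comparisons as changed, every array of one group lay above every array of the other.

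Of 12 measured neural crest specifiers 8 rose, 0 fell and 4 did not pass (8 and 0 adjusted over the list alone), with a median log2 fold change of 2.54. The list was shifted upward by camera at adjusted p = 3.33e-05, but at adjusted p = 0.0975 with an estimated correlation. The list as fixed also holds rpe65, which encodes the retinoid isomerase of the visual cycle. It is among the higher members in each of the 4 comparisons, with rpe65.S 13-fold higher here (adjusted p = 7.07e-07). Without rpe65, an alternative chosen after the data were seen, 7 of 11 rose here and the list had adjusted p = 0.000231, and adjusted p = 0.0975 with an estimated correlation. Of 11 neural border specifiers 7 rose, 2 fell and 2 did not pass (7 and 2 adjusted over the list alone), with a list adjusted p = 0.00884, and adjusted p = 0.0975 with an estimated correlation. The homeobox genes msx1.L and msx2.L rose 4.75-fold and 8.31-fold, zic5.S rose 22.1-fold (adjusted p = 8.71e-07) and hes4.L rose 3.09-fold. The list test takes the brightest probe set of a gene. For pax3 that is one of those that did not follow pax3.S (0.58, SE 0.5, adjusted p = 0.418). The pax3.S probe set rose 9.61-fold (log2 fold change 3.27, SE 0.5, adjusted p = 0.000518), and pax3.L rose 14.7-fold (adjusted p = 6.89e-05). The plate arrays stood apart for both probe sets, as their SDs above show, so the size of these folds is imprecise. By contrast, zic1.S fell by 0.92 on the log2 scale (SE 0.11, adjusted p = 0.000127), and its dimmer probe set fell by 1.43 (SE 0.2, adjusted p = 0.000358). Among 18 neural crest effector and migration genes 13 rose, 1 fell and 4 did not pass (13 and 1 adjusted over the list alone), with a list adjusted p = 0.000362, and adjusted p = 0.0975 with an estimated correlation. They included pdgfra.L, a growth factor receptor gene, at 9.35-fold (adjusted p = 1.87e-06), the matrix metalloproteinase gene mmp14.L at 4.57-fold and the ephrin gene efnb2.S at 3.92-fold.

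Of 21 early ectoderm and pluripotency-associated genes 17 fell, 2 rose and 2 did not pass (18 and 2 adjusted over the list alone), with a median of -1.62. The list was shifted downward at adjusted p = 6.66e-07, and at adjusted p = 0.0975 with an estimated correlation. The POU class V gene pou5f3.2.L fell 65.1-fold, from 11.46 ± 0.53 (SD, n = 2) to 5.43 ± 0.53 (SD, n = 3), and the forkhead gene foxd4l1.1.S fell 19.8-fold (adjusted p = 1.4e-07). The BMP ligand gene bmp7.2.L fell 38-fold (adjusted p = 8.5e-07), bmp4.S fell 5.55-fold and twsg1.L, which encodes a BMP-binding protein, fell 6.85-fold. The BMP list itself, with 5 of 24 members higher, 10 lower and 9 not past, was not shifted (adjusted p = 0.177; 5 and 11 adjusted over the list alone). The caudal gene cdx1.S fell 16.6-fold and the brachyury gene tbxt.S fell 6.67-fold. Of 24 Wnt genes 12 rose, 4 fell and 8 did not pass (12 and 4 adjusted over the list alone), with a list adjusted p = 0.0124, and adjusted p = 0.424 with an estimated correlation. The list was not shifted when dim probe sets were left out (adjusted p = 0.0905, range over the alternatives 0.00785 to 0.0905). The ligand gene wnt8a.L rose 13.5-fold (adjusted p = 4.39e-07), the receptor genes fzd10.S and fzd3.L rose 6.08-fold and 5.38-fold, and sp5l.S, an Sp-family zinc finger gene, fell 6.25-fold.

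Some genes of other cell types rose in the border as well. The keratin gene krt12.4.S rose 72-fold, from 3.36 ± 0.07 (SD, n = 2) to 9.53 ± 0.66 (SD, n = 3), with adjusted p = 9.91e-07. The secreted lectin gene itln1.L rose 37.3-fold and krt70.L rose 31.2-fold. The gene olfm4.L, which is in none of the lists and is not assigned to a cell type here, rose 52.9-fold. The epidermis list was not shifted (9 of 35 higher, 3 lower, 23 not past; adjusted p = 0.208). The β-tubulin gene tubb2b.S rose 14.8-fold, and 8 of 21 neuronal differentiation genes were higher, 1 lower and 12 not past (10 and 1 adjusted over the list alone), with a list adjusted p = 0.0983 that became 0.0376 without neural plate replicate 2 (range over the alternatives 0.0376 to 0.217). The cement gland and hatching gland list was shifted upward (4 of 9 higher, 0 lower, 5 not past; adjusted p = 0.0118, and adjusted p = 0.0975 with an estimated correlation), led by xa-1.L at 43.3-fold. Of 64 ribosomal protein genes 59 rose, 1 fell and 4 did not pass (60 and 1 adjusted over the list alone), with a median of 0.94, a list adjusted p = 1.39e-18, and adjusted p = 0.204 with an estimated correlation. Examples were rpl8.S at 4.01-fold (adjusted p = 3.19e-06) and rpl35a.S at 3.89-fold. The 3' minus 5' difference of the array's control probe sets was 0.42 (SE 0.13) higher in the plate than in the border for beta actin and 0.01 (SE 0.21) higher for Gapd. Cell cycle genes went both ways (11 of 43 higher, 18 lower, 14 not past; adjusted p = 0.149), with the cyclin gene ccnb1.S 14.4-fold lower and the replication gene mcm6.2.L 6.03-fold higher.

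The 15 lists that were not shifted in this comparison had adjusted p from 0.0503 to 0.987. The lowest was that of placode and preplacodal genes (5 of 13 higher, 1 lower, 7 not past; range over the alternatives 0.0267 to 0.0899). It passed after quantile normalization (0.0471), with only the arrays compared (0.0302), with the mean of a gene's probe sets (0.0446), without neural plate replicate 2 (0.0267), without stage 14 border replicate 3 (0.047), without stage 18 border replicate 1 (0.0461) or 2 (0.0463), and without anterior neural fold replicate 1 (0.0415), 2 (0.0413) or 3 (0.0406). The placode list also passed with the replicate number as a block (0.0268). Median, mean and test differed in sign for the neural plate progenitor, blood, Hox and retinoic acid lists. Stage and tissue changed together in this comparison.

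The comparison of the neural border at stages 18 and 14 asked how crest-forming tissue changes as the folds rise. The largest rise among named genes was that of astl3a.1.L, which encodes a metalloprotease of the astacin family that holds the hatching enzymes, 31.5-fold higher at stage 18 (8.93 ± 0.06, SD, n = 2, against 3.96 ± 0.38, SD, n = 3; log2 fold change 4.98, SE 0.38, adjusted p = 0.000917). The crest gene sox10.L rose 3.41-fold, from 5.25 ± 0.33 (SD, n = 3) to 7.01 ± 0.33 (SD, n = 2), with a log2 fold change of 1.77 (SE 0.23, adjusted p = 0.00324). The intermediate filament gene prph.S rose 6.09-fold (log2 fold change 2.61, SE 0.21, adjusted p = 0.000917). The largest fall among named genes was that of the homeobox gene crx.L, 6.35-fold, from 7.7 ± 0.11 (SD, n = 3) to 5.03 ± 0.14 (SD, n = 2), with adjusted p = 0.000504. In all, 1016 probe sets (6.56%) changed, 585 higher and 431 lower at stage 18, and 358 changed at least 2-fold. With arrays centred on their medians the split turned, with 501 higher and 574 lower of 1075, or 46.6% higher against 57.6% as deposited.

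Of 12 neural crest specifiers 3 rose, 0 fell and 9 did not pass (5 and 0 adjusted over the list alone), with a list adjusted p = 0.00607, and adjusted p = 0.311 with an estimated correlation. Without rpe65, 2 of 11 rose (adjusted p = 0.0168, and adjusted p = 0.311 with an estimated correlation). Beside sox10.L, the ETS factor gene ets1.L rose 2.71-fold (log2 fold change 1.44, SE 0.25, adjusted p = 0.00989), which did not pass when only the arrays compared were modelled (adjusted p = 0.061, range over the alternatives 0.0047 to 0.061). Of 11 neural border specifiers 0 were higher, 4 lower and 7 not past (0 and 4 adjusted over the list alone). The list was shifted downward at adjusted p = 0.0408, and at adjusted p = 0.311 with an estimated correlation. It was not shifted without stage 14 border replicate 1 (0.0913), without stage 18 border replicate 1 (0.0778) or without anterior neural fold replicate 3 (0.0519), nor after quantile normalization (0.0563), median centring (0.0621), without dim probe sets (0.0557) or with only the arrays compared (0.0747). With the replicate number as a block it was not shifted either (0.0695). Its adjusted p ranged from 0.0129 to 0.0913 over the alternatives. All 4 that fell were zic genes. The zic4.L level fell by 1.23 on the log2 scale (SE 0.15, adjusted p = 0.00262) and zic1.S fell by 0.66 (SE 0.11, adjusted p = 0.0094), while pax3.S differed by -0.22 (SE 0.5, adjusted p = 0.863) and pax3.L by -0.44 (SE 0.43, adjusted p = 0.636). Of 18 effector and migration genes 2 rose and 1 fell (adjusted p = 0.213).

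The epidermis, gland and multiciliated cell lists were shifted upward with the preset correlation. Of 35 epidermis genes 8 rose, 0 fell and 27 did not pass (9 and 0 adjusted over the list alone), with a list adjusted p = 0.000661, and adjusted p = 0.311 with an estimated correlation. Among them itln1.L rose 7.53-fold, from 9.3 ± 0.82 (SD, n = 3) to 12.21 ± 0.18 (SD, n = 2). Of 9 cement gland and hatching gland genes 4 rose, 0 fell and 5 did not pass (6 and 0 adjusted over the list alone), with a list adjusted p = 0.00142, and adjusted p = 0.197 with an estimated correlation. Of 11 multiciliated cell genes 3 rose, 0 fell and 8 did not pass, with a list adjusted p = 0.00607, and adjusted p = 0.355 with an estimated correlation. That list was not shifted without stage 18 border replicate 2 (adjusted p = 0.107, range over the alternatives 1.22e-05 to 0.107), in which the cilium gene tekt4.S read 6.78 against 5.43 in replicate 1. Its member tekt2.S rose 3.07-fold (adjusted p = 0.00391). Of 21 neuronal genes 5 rose, 1 fell and 15 did not pass (7 and 2 adjusted over the list alone), with a list adjusted p = 0.00646, and adjusted p = 0.355 with an estimated correlation. This list was not shifted without stage 18 border replicate 1 (adjusted p = 0.119, range over the alternatives 0.00384 to 0.119). The LIM homeobox gene lhx5.S fell 2.74-fold (adjusted p = 0.00356). The level of lhx5.S at stage 18 (3.52) and that of tekt2.S at stage 14 (2.9) lay within background.

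The anterior neural, early ectoderm and cell cycle lists were shifted downward with the preset correlation. Of 18 anterior neural and forebrain genes 3 fell, 0 rose and 15 did not pass (7 and 0 adjusted over the list alone), with a median of -0.41, a list adjusted p = 0.000661, and adjusted p = 0.355 with an estimated correlation. Of 21 early ectoderm and pluripotency-associated genes 5 fell, 0 rose and 16 did not pass (6 and 0 adjusted over the list alone), with a list adjusted p = 0.000661, and adjusted p = 0.311 with an estimated correlation. Examples were dppa2.L, 2.9-fold lower (adjusted p = 0.00781), and the maternal-effect gene zar1.S, 2.36-fold lower (adjusted p = 0.00362). Of 43 cell cycle genes 4 fell, 0 rose and 39 did not pass (6 and 0 adjusted over the list alone), with a list adjusted p = 0.00607, and adjusted p = 0.311 with an estimated correlation. Among signalling genes, bmp7.2.L fell 3.72-fold (adjusted p = 0.00432), wnt8a.L fell 2.35-fold (adjusted p = 0.00329), fst.L, which encodes the BMP and activin binding protein follistatin, rose 3.61-fold (adjusted p = 0.00115), and sfrp2.S, a secreted Frizzled-related gene, rose 2.75-fold (adjusted p = 0.00163). The Hox gene hoxa3.S rose 2.76-fold (adjusted p = 0.00204).

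The 13 lists not shifted between these stages had adjusted p from 0.138 to 0.81, and median, mean and test differed in sign for the placode and Hox lists. The muscle list (2 of 24 higher, 0 lower, 22 not past; 5 and 0 adjusted over the list alone; adjusted p = 0.214) passed without stage 18 border replicate 2 (0.0388), without dim probe sets (0.0152) and with the mean of a gene's probe sets (0.0377), with a range over the alternatives of 0.0152 to 0.766. The ribosomal list (0 of 64 higher, 1 lower, 63 not past; adjusted p = 0.339) passed without stage 18 border replicate 2 (0.00199, range over the alternatives 0.00199 to 0.573). Counts moved with single arrays, to 458 without stage 14 border replicate 3, to 673 without stage 18 border replicate 1 (492 higher, 181 lower) and to 672 without stage 18 border replicate 2 (355 higher, 317 lower), and 233 probe sets passed when only the arrays compared were modelled.

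The comparison of the stage 18 neural border with the anterior neural fold set border tissue that forms crest against border tissue of the same stage that does not. Among named genes, crest specifiers were the leading rises. The foxd3.L level was 24-fold higher, at 8.45 ± 0.13 (SD, n = 2) against 3.87 ± 0.92 (SD, n = 3), with a log2 fold change of 4.58 (SE 0.45, adjusted p = 0.000287). The levels of tfap2b.L, snai2.L and sox10.L were 21-fold (adjusted p = 8.32e-06), 16.1-fold (adjusted p = 0.000476) and 15.2-fold (adjusted p = 7.8e-06) higher, with sox10.L within background in the fold at 3.09 ± 0.28 (SD, n = 3). Eye-field and forebrain genes were among the largest differences in the other direction, with six6.L 45.9-fold lower in the border, at 3.69 ± 0.07 (SD, n = 2) against 9.21 ± 0.45 (SD, n = 3), a log2 fold change of -5.52 (SE 0.24, adjusted p = 1.47e-06). In all, 925 probe sets (5.97%) differed, 512 higher and 413 lower in the border, and 476 by at least 2-fold.

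Of 12 neural crest specifiers 8 were higher, 0 lower and 4 not past (8 and 0 adjusted over the list alone), with a median of 1.97. The list was shifted at adjusted p = 6.78e-10, and at adjusted p = 0.0374 with an estimated correlation. Of 18 anterior neural and forebrain genes 16 were lower, 0 higher and 2 not past (18 and 0 adjusted over the list alone), with a median of -2.47, adjusted p = 1.48e-29, and adjusted p = 0.0374 with an estimated correlation. These were the only lists in this comparison that passed with an estimated correlation. The homeobox genes rax.L, six3.L and hesx1.L were 35.7-fold, 34.4-fold and 24.9-fold lower in the border, and the zinc finger gene fezf2.L 39.8-fold. In the border, six6.L (3.69), fezf2.L (3.7), rax.L and hesx1.L (both 2.87) lay within background, which limits their folds.

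Of 11 neural border specifiers 5 were higher, 2 lower and 4 not past (5 and 2 adjusted over the list alone), with a list adjusted p = 0.043, and adjusted p = 0.202 with an estimated correlation. The list did not pass without stage 14 border replicate 1 (0.0885) or 2 (0.0605), without stage 18 border replicate 1 (0.108) or 2 (0.0699), without anterior neural fold replicate 1 (0.0552), with array weights (0.0544) or with the mean of a gene's probe sets (0.108). Its adjusted p ranged from 0.0234 to 0.108 over the alternatives. The AP-2 gene tfap2a.L was 5.06-fold higher (adjusted p = 8.32e-06) and msx2.L was 4.93-fold higher (adjusted p = 9.91e-05). In this list pax3 is counted by its brightest probe set, at -0.69 (SE 0.5, adjusted p = 0.597), opposite in sign to the pax3.S and pax3.L values that follow. The pax3.S difference of 1.66 (SE 0.5, adjusted p = 0.0915) and the pax3.L difference of 1.65 (SE 0.43, adjusted p = 0.0525) did not pass. Over the alternatives their adjusted p ranged from 0.0197 to 0.283 and from 0.0247 to 0.174. Without neural plate replicate 1 or 2, arrays outside this comparison whose spread enters the pooled error, pax3.S (0.0197 in either case) and pax3.L (0.0247 in either case) passed, and pax3.L also passed without anterior neural fold replicate 3 (0.0447), after quantile normalization (0.0478), without dim probe sets (0.0298) and with a trended, robust variance (0.0421). The brighter zic1.S probe set was 1.55-fold higher (adjusted p = 0.00863), a call lost without stage 18 border replicate 2 (adjusted p = 0.0606, range over the alternatives 0.00666 to 0.0606), and the dimmer differed by 0.17 (SE 0.2, adjusted p = 0.789). Of 18 effector and migration genes 4 were higher, 2 lower and 12 not past (6 and 3 adjusted over the list alone), with a list adjusted p = 0.0408, and adjusted p = 0.235 with an estimated correlation. That list did not pass without neural plate replicate 1 (0.0537) or 2 (0.0534), stage 18 border replicate 1 (0.176) or anterior neural fold replicate 1 (0.0517), or with only the arrays compared (0.0948). Its adjusted p ranged from 0.00826 to 0.176. Its members pdgfra.L, mmp14.L and the semaphorin receptor gene nrp1.L were 6.75-fold, 5.1-fold and 3.1-fold higher, each past the threshold without any single array.

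The Wnt and Hox lists were shifted upward and the axial mesoderm and placode lists downward with the preset correlation. Of 24 Wnt genes 9 were higher, 2 lower and 13 not past (10 and 2 adjusted over the list alone), with a list adjusted p = 0.000416, and adjusted p = 0.219 with an estimated correlation. The ligand genes wnt8a.L and wnt3a.S were 8.46-fold and 4.15-fold higher in the border, and the genes of the secreted inhibitors frzb.L and dkk1.S were 8.2-fold and 4.06-fold lower. Of 21 Hox genes 4 were higher, 0 lower and 17 not past (6 and 0 adjusted over the list alone), with a list adjusted p = 0.000929, and adjusted p = 0.164 with an estimated correlation. The Hox list did not pass without dim probe sets (adjusted p = 0.78, range over the alternatives 0.000156 to 0.78). The hoxa2.L and hoxa3.S levels were 7.8-fold and 5.51-fold higher, with both genes within background in the fold. Also within background were wnt8a.L (3.46) and wnt3a.S (3.71) in the fold and frzb.L (3.33), dkk1.S (3.4) and gsc.L (3.12) in the border. Of 14 axial mesoderm and notochord genes 7 were lower, 0 higher and 7 not past (7 and 1 adjusted over the list alone), with a list adjusted p = 2.11e-05, and adjusted p = 0.0525 with an estimated correlation. Among them were shh.L, 5.6-fold lower, and gsc.L, 8-fold lower. Of 13 placode and preplacodal genes 4 were lower, 0 higher and 9 not past (5 and 2 adjusted over the list alone), with a list adjusted p = 0.0034, and adjusted p = 0.219 with an estimated correlation, led by hesx1.L and by pitx1.L at 10.9-fold lower.

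Of 43 cell cycle genes 5 were lower, 0 higher and 38 not past (6 and 0 adjusted over the list alone), with a list adjusted p = 0.000311, and adjusted p = 0.164 with an estimated correlation. The cyclin gene ccnd1.S was 2.31-fold lower (adjusted p = 0.000285). Of 21 neuronal genes 5 were higher, 2 lower and 14 not past (9 and 2 adjusted over the list alone), with a list adjusted p = 0.00652, and adjusted p = 0.286 with an estimated correlation. The neuronal list did not pass without stage 18 border replicate 1 (0.088, range over the alternatives 0.0024 to 0.088). Its RNA-binding protein gene elavl3.L was 3.88-fold higher. Of 11 multiciliated cell genes 2 were higher, 0 lower and 9 not past (5 and 0 adjusted over the list alone), with a list adjusted p = 0.00199, and adjusted p = 0.235 with an estimated correlation. The border arrays stood apart on this list, with tekt4.S at 5.43 in replicate 1 and 6.78 in replicate 2. The list had adjusted p of 9.84e-06 without stage 18 border replicate 1 and 0.0217 without replicate 2, the ends of its range over the alternatives. Of 17 endoderm genes 3 were lower, 0 higher and 14 not past (4 and 1 adjusted over the list alone), with a list adjusted p = 0.0462, and adjusted p = 0.219 with an estimated correlation. The endoderm list did not pass without neural plate replicate 1 (0.0588) or 2 (0.0591), stage 14 border replicate 1 (0.0695), 2 (0.0594) or 3 (0.0539), stage 18 border replicate 1 (0.154), or anterior neural fold replicate 1 (0.0552) or 2 (0.0708), with array weights (0.0544) or with only the arrays compared (0.0981). Its adjusted p ranged from 0.021 to 0.154. Of 64 ribosomal protein genes 0 passed in either direction by limma, over all probe sets or adjusted over the list alone (0 higher and 2 lower at an unadjusted p under 0.05), and the list, with a median of -0.08, had adjusted p = 0.0339, and adjusted p = 0.642 with an estimated correlation. The ribosomal list did not pass without anterior neural fold replicate 3 (0.131), after quantile normalization (0.079), without dim probe sets (0.0735) or with only the arrays compared (0.0585), and it turned upward without stage 18 border replicate 2 (0.532, range over the alternatives 1.71e-05 to 0.532).

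The 9 lists not shifted here had adjusted p from 0.102 to 0.926, and median, mean and test differed in sign for the neural plate progenitor and cement gland lists. They included muscle and paraxial mesoderm genes (2 of 24 higher, 1 lower, 21 not past; adjusted p = 0.138), which passed without stage 18 border replicate 2 (0.0156), without dim probe sets (0.0328) and with the mean of a gene's probe sets (0.0383), with a range over the alternatives of 0.0156 to 0.737. BMP genes (1 of 24 higher, 2 lower, 21 not past; adjusted p = 0.102) passed without anterior neural fold replicate 3 (0.0218, range over the alternatives 0.0218 to 0.671). Without dim probe sets the cement gland (0.039), epidermis (0.0219) and FGF (0.0236) lists passed, with ranges over the alternatives of 0.039 to 0.773, 0.0219 to 0.795 and 0.0236 to 0.532. Of the 2 muscle list members that were higher, pcdh8l.S (10.9-fold, adjusted p = 1.79e-05) encodes a protocadherin and mylpf.L a muscle myosin light chain, the latter at 5.93 in stage 18 border replicate 1 and 4.43 in replicate 2 (log2 fold change 1.79, adjusted p = 0.0164). The mylpf.L difference did not pass without anterior neural fold replicate 2 (0.0568) or with only the arrays compared (0.0682). Its adjusted p ranged from 0.000658 to 0.0682. The follistatin gene fst.L was 7.11-fold higher and tll1.S, a tolloid-like protease gene, 5.69-fold lower. The border level of tll1.S (3.18) and the fold level of mylpf.L (3.4) lay within background. The cement gland gene agr2.L was 41.3-fold lower (adjusted p = 0.000337). The count fell to 543 without stage 18 border replicate 2 and to 611 without anterior neural fold replicate 3.

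The comparison of the stage 14 neural border with animal cap of the same stage set crest-forming tissue against epidermis. The title genes were among the largest rises of named genes. The pax3.S level was 66.8-fold higher in the border (log2 fold change 6.06, SE 0.63, adjusted p = 9.38e-05) and zic1.S was 56.9-fold higher (log2 fold change 5.83, SE 0.14, adjusted p = 2.3e-08), with pax3.L 24.7-fold higher (adjusted p = 0.000183). The crest genes sox9.S, snai2.L and foxd3.L were 47.8-fold (adjusted p = 7.09e-06), 37.6-fold (adjusted p = 0.000103) and 34.6-fold (adjusted p = 0.000147) higher. In the other direction szl.L, which encodes the secreted BMP feedback inhibitor sizzled, was 60.3-fold lower, at 2.46 ± 0.04 (SD, n = 3) in the border and 8.38 in the cap (log2 fold change -5.91, SE 0.13, adjusted p = 1.82e-08). In all, 4785 probe sets (30.9%) differed, 2343 higher and 2442 lower in the border, and 2566 by at least 2-fold. The cap levels of pax3.S, pax3.L, snai2.L, foxd3.L and sox9.S (3.01, 3.23, 2.83, 2.78 and 3.47) and the border level of szl.L lay within background. These folds are limited by that floor.

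Of 11 neural border specifiers 9 were higher, 0 lower and 2 not past (9 and 0 adjusted over the list alone), with a median of 1.63. The list was shifted at adjusted p = 7.11e-07, and at adjusted p = 0.0293 with an estimated correlation. It counts pax3 as not past, by its brightest probe set (-1.36, SE 0.64, adjusted p = 0.138) and not by pax3.S. Of 24 BMP genes 16 were lower, 2 higher and 6 not past (16 and 3 adjusted over the list alone), with a median of -1.42, adjusted p = 7.11e-07, and adjusted p = 0.0379 with an estimated correlation. Beside szl.L these were bmp7.2.L, 39.7-fold lower, the pseudoreceptor gene bambi.L, 30.5-fold lower, and twsg1.L, 25.3-fold lower. No other list in this comparison passed with an estimated correlation. Of 12 neural crest specifiers 8 were higher, 0 lower and 4 not past (8 and 0 adjusted over the list alone), with a median of 2.22, adjusted p = 1.39e-05, and adjusted p = 0.0923 with an estimated correlation. Of 18 effector and migration genes 11 were higher, 0 lower and 7 not past (11 and 1 adjusted over the list alone), with a list adjusted p = 5.78e-05, and adjusted p = 0.0923 with an estimated correlation. The Eph receptor gene epha4.L was 5.9-fold higher and pdgfra.L was 8.19-fold higher.

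Of 21 neural plate progenitor genes 15 were higher, 2 lower and 4 not past (15 and 3 adjusted over the list alone), with a median of 1.85, adjusted p = 6.47e-07, and adjusted p = 0.125 with an estimated correlation. The sox11.S, irx1.L and zeb2.S levels were 19.7-fold, 19.7-fold and 18.9-fold higher, with zeb2.S within background in the cap (3.12). Of 18 anterior neural genes 6 were higher, 0 lower and 12 not past (6 and 0 adjusted over the list alone), with a list adjusted p = 0.014, and adjusted p = 0.436 with an estimated correlation, among them otx1.L and otx2.S at 6.83-fold and 6.39-fold. Of 24 Wnt genes 15 were higher, 1 lower and 8 not past (15 and 1 adjusted over the list alone), with a list adjusted p = 7.35e-07, and adjusted p = 0.126 with an estimated correlation. The wnt8a.L level was 15.2-fold higher and that of axin2.S, a feedback target of Wnt signalling, 14.2-fold higher. Of 15 FGF genes 4 were higher, 0 lower and 11 not past (adjusted p = 0.0178, and adjusted p = 0.264 with an estimated correlation), with fgfr1.L 4.99-fold higher. Of 15 retinoic acid pathway genes 6 were higher, 3 lower and 6 not past (7 and 3 adjusted over the list alone), with a list adjusted p = 0.0419, and adjusted p = 0.287 with an estimated correlation. The retinoic acid list did not pass without stage 14 border replicate 1 (0.0506) or with the mean of a gene's probe sets (0.0926), with a range over the alternatives of 0.00341 to 0.0926. The retinoic acid hydroxylase gene cyp26c1.S was 46.6-fold higher.

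The epidermis, multiciliated cell and blood lists were shifted downward with the preset correlation. Of 35 epidermis genes 17 were lower, 0 higher and 18 not past (17 and 0 adjusted over the list alone), with a median of -0.93, adjusted p = 6.82e-06, and adjusted p = 0.138 with an estimated correlation. The transcription factor genes gata2.L, foxi4.2.S and grhl3.L were 18.5-fold, 16.8-fold and 9.24-fold lower, with grhl3.L within background in the border (2.67). Of 11 multiciliated cell genes 4 were lower, 0 higher and 7 not past (4 and 0 adjusted over the list alone), with a list adjusted p = 0.0362, and adjusted p = 0.436 with an estimated correlation. The multiciliated list did not pass without stage 14 border replicate 1 (0.0502) or with the mean of a gene's probe sets (0.0777, range over the alternatives 0.00937 to 0.0777), and ccno.L, a cyclin gene of multiciliated cells, was 4.56-fold lower. Of 24 blood and lateral mesoderm genes 6 were lower, 0 higher and 18 not past (6 and 0 adjusted over the list alone), with a list adjusted p = 0.0419, and adjusted p = 0.436 with an estimated correlation. The blood list did not pass without stage 14 border replicate 1 (0.0517), without stage 18 border replicate 1 (0.0536) or 2 (0.0551), after quantile normalization (0.174) or with only the arrays compared (0.0609). With the replicate number as a block it did not pass either (0.0697). Its adjusted p ranged from 0.0337 to 0.174. Of 43 cell cycle genes 16 were higher, 6 lower and 21 not past (16 and 7 adjusted over the list alone), with a list adjusted p = 0.00626, and adjusted p = 0.255 with an estimated correlation. The replication genes mcm4.L and pcna.L were 11.9-fold and 4.72-fold higher. Of 64 ribosomal protein genes 24 were higher, 0 lower and 40 not past (27 and 0 adjusted over the list alone), with a median of 0.41, adjusted p = 7.11e-07, and adjusted p = 0.436 with an estimated correlation.

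The 8 lists not shifted against the cap had adjusted p from 0.412 to 0.991, and median, mean and test differed in sign for the placode, cement gland and Hox lists. They included neuronal genes (3 of 21 higher, 1 lower), in which tubb2b.S was 2.74-fold higher and the synaptic vesicle gene syt1.L 6.48-fold lower. The cap had 1 array, so the direction of each difference from it rests on that array.

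**Figure D2:**
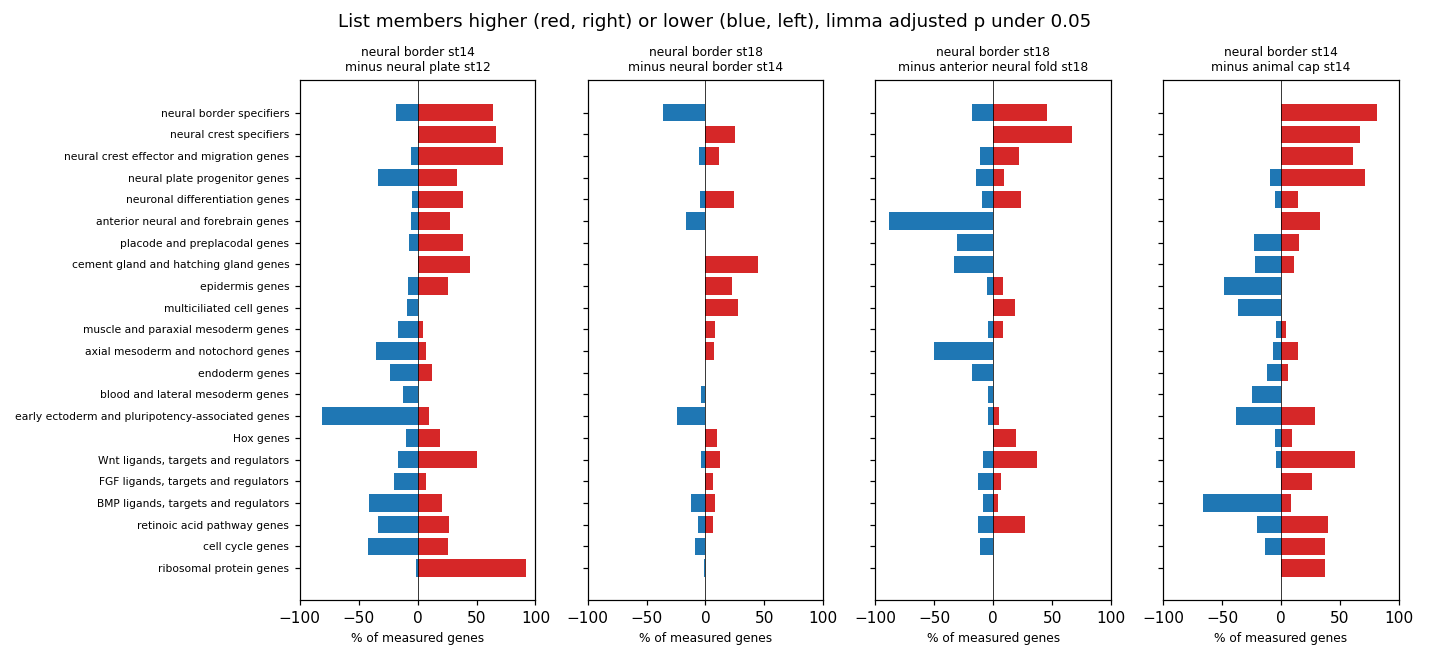
Share of the measured genes of each list (vertical axis, 22 lists) that were higher (red, to the right) or lower (blue, to the left) in the first tissue of each of the 4 comparisons at a limma adjusted p under 0.05, in percent (horizontal axis). Anterior neural and forebrain genes reach 16 of 18 lower against the anterior neural fold, and ribosomal protein genes 59 of 64 higher against the stage 12 neural plate.

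The last 2 comparisons share no arrays, but both use the spread that 1 model estimated for each probe set. A probe set with a small estimated spread passes more easily in both. Genes higher in the neural border than in both reference tissues were counted across these comparisons. They numbered 172 probe sets (88 named genes), against 77.4 for independent sets of 512 and 2343 (odds ratio 2.98, 95% confidence interval 2.46 to 3.62, Fisher's exact test p = 3.54e-26, adjusted p = 1.42e-25 over the 4 pairs of directions). Of the fixed lists, 7 of 12 crest specifiers and 8 of 24 Wnt genes were among them. So were 4 of 11 border specifiers and 3 of 18 effector and migration genes. The neural plate progenitor, neuronal and Hox lists had 2 of 21 each. The anterior neural, epidermis, cell cycle and ribosomal lists had 0 of 18, 0 of 35, 0 of 43 and 0 of 64. These counts of 0 were fixed by the single comparisons and form no contrast of their own. Of the anterior neural, cell cycle and ribosomal lists, 0 genes were higher than in the fold. Of the epidermis list, 0 genes were higher than in the cap. The log2 fold changes of foxd3.L were 4.58 against the fold and 5.11 against the cap, those of tfap2b.L were 4.39 and 4.32, those of snai2.L were 4.01 and 5.23, and those of sox10.L were 3.92 and 2.67. Outside the naming rule, and chosen after their values were seen, ror2.L was at 2.56 and 3.8 and meis3.S at 2.55 and 2.39. Other pairs of directions also overlapped. Probe sets lower than in the fold and higher than in the cap numbered 145, against 62.5 (odds ratio 3.17, Fisher's exact test p = 1.82e-24), and those higher than in the fold and lower than in the cap numbered 124, against 80.7 (odds ratio 1.75, Fisher's exact test p = 4.91e-07). Those lower than in both numbered 56, against 65.1 (odds ratio 0.834, Fisher's exact test p = 0.244). The numbers for independent sets, and the Fisher tests, take no account of the shared estimate of spread. They also span all tested probe sets, including those within background, which can hardly pass in either comparison. This can make the numbers for independent sets too low. Probe sets of the same gene, such as those of pdgfra.L, were counted separately, which can make the p-values too small. The cap side of each pair rests on 1 array. The comparisons were made at different stages, 18 and 14.

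**Figure D3:**
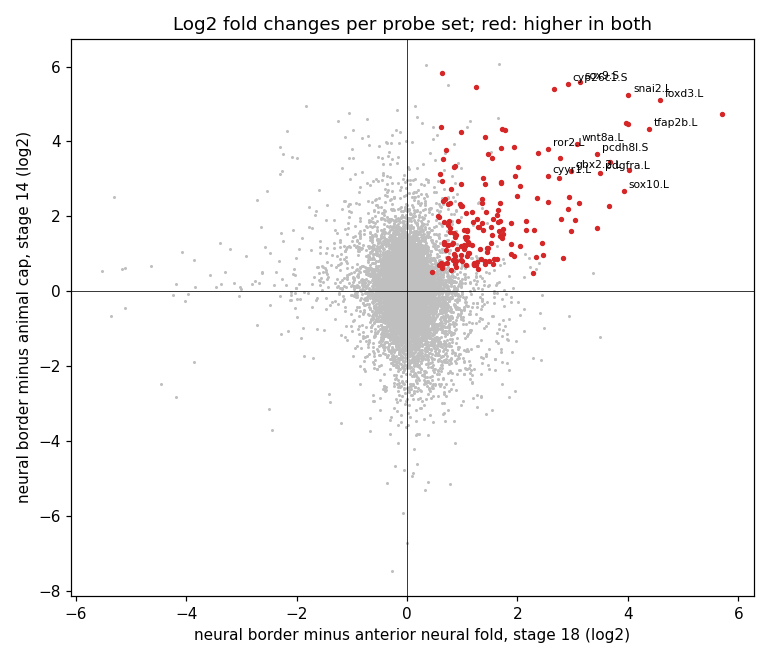
Log2 fold change of each tested probe set between neural border and anterior neural fold at stage 18 (horizontal axis) and between neural border and animal cap at stage 14 (vertical axis), with the 172 probe sets past the threshold and higher in the border in both shown in red. The labelled genes include foxd3.L at 4.58 and 5.11 and sox10.L at 3.92 and 2.67.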

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

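The tests of explanations in this part were chosen after the values they bear on had been seen. The array's own control probe sets were in no comparison of the report, and some of those named a1Act and a3Act on the array read higher in each neural border array of a stage than in any array of the reference tissues (anterior neural fold and animal cap). At stage 14 the border means lay above the reference means by 1.25 (3' a1Act probe set) and 1.34 (middle a1Act probe set) on the log2 scale. At stage 18 the differences were 2.99 (3'), 2.15 (5') and 2.54 (middle) for a1Act, and 1.98 (3'), 1.44 (5') and 1.14 (middle) for a3Act. The 2 arrays at stage 18 stood apart, with a1Act at 7.12, 7.44 and 7.89 (3', 5', middle) in replicate 1 and at 4.78, 5.55 and 6.31 in replicate 2, against highest reference values of 3, 4.53 and 4.67. For a3Act the values were 5.76, 5.02 and 4.75 in replicate 1 and 3.91, 3.74 and 3.69 in replicate 2, against 3.02, 2.99 and 3.17. No table used here names the gene behind these probe sets.

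The tables argue against beta actin transcripts binding the a1Act probes, since the array's beta actin controls differed by -0.16 (SE 0.21) between the stage 18 border and the anterior neural fold, where a1Act differed by 2.6 (SE 0.73). Muscle-forming tissue carried with the explant stays open as a candidate explanation. The median difference of the muscle and paraxial mesoderm list between stage 18 replicates 1 and 2 was 0.17, at percentile 99.3 of random lists of matched level (95% range -0.08 to 0.14), but acta1.S (2.82 and 2.81) and myod1.L (3.52 and 3.64) read alike at or near background, and the largest differences were those of mylpf.L (5.93 and 4.43), ckm.L (4.87 and 3.51, against 5.94 in the animal cap), pcdh8.2.L (5.25 and 4.61) and tnni2.S (5.59 and 5.13). Many other members of the muscle list, such as tnnc2.L (3.25 and 3.2), myf6.L (3.27 and 3.05) and myh8.L (3.13 and 2.92), lay within background in both arrays. The list's median therefore rests partly on floor values. A difference between the crest-forming border and the other tissues in the gene that the a1Act probes bind was not tested.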

How the results depend on the processing

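The counts of changed probe sets, in the order plate, stage, fold and cap, kept within 1.5 times their size under quantile normalization, median centring, the filter on dim probe sets, trend and robust variance, array weights and averaging by gene. With a 2-fold minimum, fewer by construction, they were 2744, 358, 476 and 2566, with 97 probe sets higher in the neural border than in both references. With an estimated list correlation 0, 0, 2 and 2 lists were shifted. That test estimates the correlation of list members from the arrays, which leave 6 residual degrees of freedom, instead of presetting it. How much of the fall comes from correlation of the list members was not tested. Between the stages, 233 probe sets passed with only the arrays compared, and 224 of these were among the 1016. That setting leaves fewer degrees of freedom in each comparison. Against the plate and the fold, which have as many arrays, 6184 and 716 passed, where all arrays gave 6352 and 925. Why the fall between the stages was larger was not tested. The calls between the stages depend largely on arrays outside that comparison, which enter the pooled spread. With the replicate number as a block 620 passed, 580 of them among the 1016, and the cause was not tested. With that block the border specifier list between the stages (0.0695) and the blood list against the cap (0.0697) did not pass, the placode list against the plate did (0.0268), and no other list call changed. Whether that number pairs samples was not settled. Same-numbered arrays correlated beyond their groups at -0.102 to 0.257, and between the border stages at 0.163 and 0.094. Of the 13 same-numbered pairs 2 lay over 0.1, and pairs with different numbers ranged from -0.28 to 0.28. In 5 of 26 tests an array's best partner had its own number, fewer than random partners among 2 or 3 arrays would give on average. These tests are not independent, since in a group of 2 arrays the values centred on the group mirror each other. Without single arrays the counts ran from 4418 to 6543, 458 to 1016, 543 to 1058 and 3902 to 4980, the overlap from 138 to 189, and the shifted lists from 7 to 9, 7 to 10, 9 to 13 and 11 to 14. The lowest counts came without stage 14 border replicate 3 (458) and without stage 18 border replicate 2 (543), and 611 passed against the fold without its replicate 3, 673 and 672 between the stages without stage 18 border replicates 1 and 2. The ribosomal list against the fold turned upward without stage 18 border replicate 2 (0.532; range 1.71e-05 to 0.532), and the cause was not tested. Without rpe65, chosen after seeing the data, the crest specifier list passed in each comparison (0.000231, 0.0168, 1.22e-08 and 2.14e-05), and with an estimated correlation against the fold (0.0333). Of the named genes that passed, 84 of 95, 33 of 68, 57 of 80 and 89 of 93 passed without any single array, and 0 reversed. Where an array left out leaves a group with 1 array, that array is assumed to vary like the others, and the lone animal cap array was not left out of its own comparison. The trend and robust setting does not act on the lists. Levels under 3.72 lie within the tag controls' background and limit the folds that rest on them.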

Other observations

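In this part the tests of explanations, and the examples of gene pairs, were chosen after their values had been seen. Xenopus laevis carries many genes as L and S copies from an ancestral genome duplication, and 1017 such pairs had a probe set for each copy. Where both copies passed in a comparison they mostly moved the same way, in 263 of 299 pairs between stage 14 border and plate, 13 of 14 between the border stages, 30 of 30 against the anterior neural fold and 209 of 219 against the animal cap. Their log2 fold changes correlated across genes at 0.58, 0.43, 0.65 and 0.67. The changes of the copies were unequal in 371, 61, 56 and 227 pairs by limma on the difference. Between plate and border, snai2.L rose by 5.48 on the log2 scale and snai2.S by 1.14 (difference 4.33, SE 0.44, adjusted p = 2.82e-05). Against the anterior neural fold, six3.L lay at -5.1 and six3.S at -0.12 (difference -4.98, SE 0.28, adjusted p = 1.08e-06). The copies of atg16l1 went opposite ways between plate and border, with 1.6 for L and -2.34 for S (difference 3.94, SE 0.25, adjusted p = 1.11e-06). Between the border stages, prph.S rose by 2.61 and prph.L differed by 0.63 (difference -1.97, adjusted p = 0.00107). Such a difference shows unequal change of 2 probe sets, which differ in sequence as well as in the copy they are assigned to. Whether a probe set also binds transcripts of the other copy could not be examined. Agreement of the 2 probe sets therefore does not show that both copies changed.

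Genes of epidermal cell types differed between the 2 arrays of the stage 18 border, with tekt4.S at 5.43 and 6.78, dynlrb2.S at 4.4 and 5.87, dnai1.L at 4.99 and 6.04 and foxi1.L at 4.42 and 6.06 in replicates 1 and 2. The multiciliated list, which holds the first 3 of these genes, had a median difference of 0.87, at percentile 100 of random lists of matched level (95% range -0.23 to 0.16), which restates the pattern and tests no explanation of it. An array-wide difference in intensity was not decided, since the median difference over all probe sets, -0.039 for replicate 2 minus 1, is held near 0 by the common scale of the deposited arrays. Unequal amounts of surface epidermis in the explants may play a part, and stay open. The epidermis list had a median of 0, at percentile 68.8 (95% range -0.13 to 0.07). Many of its members, such as krt57.L (2.94 and 2.87) and krt51.L (3.24 and 2.97), lay within background in both arrays and say little. Most brighter members were higher in replicate 2, such as ppl.L (7.18 and 8.13), krt12.4.L (10.55 and 11.27) and evpl.L (8.33 and 9.07). Others were not, such as tp63.L (5.05 and 4.71) and dsp.L (7.72 and 7.62). The group holds 2 arrays, so differences between embryos stay open, untested.

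Ribosomal protein genes were shifted upward between the stage 12 plate and the stage 14 border, with a median of 0.94 (adjusted p = 1.39e-18, and adjusted p = 0.204 with an estimated correlation). Random lists of matched level had medians of 0.05 to 0.33 (95% range), so bright probe sets tended upward and may account for part of the shift. The tables argue against such a bias as the whole of it, since the list lay at percentile 100 of the matched lists. A loss of 5' signal in the plate arrays cannot be told apart from a change in these genes, because the 3' minus 5' differences of the array's controls, plate minus border, were 0.01 (SE 0.21) for Gapd and 0.42 (SE 0.13) for beta actin. Against the animal cap, at the same stage as the border, the list's median was 0.41, where matched lists had medians of 0.05 to 0.3 (95% range). Stage and tissue stay open as well, untested, since the design does not separate them.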
